A study of Mus musculus with 6 samples.

How the data were processed

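The samples were 6 libraries of bulk RNA from mouse bone marrow-derived macrophages, 3 of the Ctrl and 3 of the KAT7KO genotype, each described in the labels as a biological replicate. Groups and replicate numbers were taken from the sample titles. Whether the 3 replicates of a genotype came from different animals is not stated, so p-values measure the spread between these libraries.

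One deposited table held all values. Its count columns hold whole-number raw counts per gene that the authors deposited for each library, with no normalization. Its FPKM columns hold, per the file headers, the authors' counts scaled to gene length and library size, for each library. The authors' log2 fold change, KAT7KO over Ctrl, stood in the same deposited table. The deposited p-value and adjusted p-value columns are likewise the authors' own. FastQC, fastp, HISAT2, featureCounts, DESeq2 and the mouse genome build GRCm39 are named in the submitters' processing notes, without versions or roles. Strand settings and the treatment of reads that match several genes are not given in the sources used here. The authors' adjusted p was exactly 1 for 4897 genes, all with a mean count of 6 or less. All columns of per-sample values were used. The reference at hand was of build GRCm38, so no coordinates are given, and its RefSeq table (GRCm38.p6) served only to match symbols to synonyms and for the order of genes.

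The table held 18039 genes, of which 12483 passed edgeR's filterByExpr by group and were tested. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest), KAT7KO against Ctrl without a block, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM after TMM scaling, as mean ± SD of 3 libraries where an SD is given. Intervals are at 95% from the moderated degrees of freedom. Library totals lay between 19906726 and 20660090 counts, so a count of 3 in a library is 0.145 to 0.151 CPM. Between replicates the mean chi-square per gene was 3.65 to 18.8 in Ctrl and 2.63 to 3.38 in KAT7KO, above the 1 that sampling noise gives. No library was therefore counted as another one sequenced again. Separate preparations from 1 culture could also exceed 1, so these values do not show that the replicates were independent cultures or animals.

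Gene lists were written before the data were examined. They cover MYST complex partners, other lysine acetyltransferases and deacetylases, extracellular trap machinery, extracellular DNA clearance, glycolysis, oxidative phosphorylation, NF-kB targets, type I interferon response and alternative activation. They also cover cholesterol synthesis, cholesterol efflux, lipid handling, macrophage identity, MHC class II and class I, lysosome and phagocytosis, S phase, G2/M, p53 targets, Hox and progenitor genes, unfolded protein response, oxidative stress and chemotactic receptors. Cell type lists were for neutrophils, B cells, T and NK cells, dendritic cells, erythroid and megakaryocyte cells, mast cells, stroma, endothelium and osteoclasts. Quality lists held immediate-early genes, ribosomal proteins, mitochondrial transcripts and sex-linked genes, the last as values with no test. Lists with at least 3 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 34 lists. Members were also adjusted over each list alone. Plin2 stood on the DNA clearance list in error, and the list was kept as written.

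The genes named were fixed by rule before the data were examined: Kat7 and Ccar2; the 10 genes higher and 10 lower with the largest log2 fold change among those past the threshold with a mean of at least 1 CPM and no overlap of the genotypes, leaving out unnamed gene models; and from each list up to 4 members past the threshold in order of p, filled to 2 with the members of highest level. Other genes are named where a small count included them or where the subject of the series called for it, and were then chosen after their values were seen.

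Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, and a test for a change over 1.2-fold (glmTreat). Lists were also tested with an estimated correlation and with fry. Added after seeing the data were the removal of a loess trend (span 0.5) of each library's log2 CPM on gene length, and the DNA clearance list less Plin2. Gene length was derived from the ratio of count to FPKM.

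On simulated counts for the 12483 genes, with 200 changed, edgeR found 44% of those changed 1.3-fold, 66% at 1.5-fold, 76% at 2-fold and 98% at 4-fold. Of its 167 calls, 11 were of unchanged genes. Camera found a simulated list of 25 moved genes and called 0 of 30 unmoved lists, whose simulated genes vary independently of each other. Removing the length trend brought a simulated correlation of fold change with length from -0.26 to -0.0055.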

Results

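Gene expression was measured by paired-end sequencing of bulk RNA from bone marrow-derived macrophages, which are macrophages grown in culture from mouse marrow precursors. The cells had been kept for 7 days with M-CSF, the growth factor that drives macrophage differentiation, at 20 ng/mL. There were 2 genotypes, Ctrl and KAT7KO, with 3 libraries each, which the labels call biological replicates. KAT7, also called HBO1, is a lysine acetyltransferase of the MYST family that acetylates histones. The series title also names the protein CCAR2, its lactylation, the release of extracellular traps by macrophages, and atherosclerosis. Protein lactylation and traps were not measured here, so the comparison is of RNA levels between the genotypes. The 6 libraries held 19906726 to 20660090 counts over genes, and 15890 to 16198 genes had at least 1 count.

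KAT7KO macrophages carried less Kat7 RNA and lower levels of mitotic genes, interferon-response genes, lipoprotein lipase and the integrin gene Itgb3 than Ctrl macrophages. Of 10 measured genes of MHC class II presentation, 5 rose, the costimulatory ligand gene Cd86 among them, as did 17 of 26 nuclear genes of oxidative phosphorylation. Neither list kept its call when gene correlation was estimated (adjusted p = 0.208 and adjusted p = 0.451 with an estimated correlation). Among genes of the trap machinery, Mmp9, Ripk3 and the histone-citrullinating enzyme Padi4 fell. With edgeR's quasi-likelihood test, 2987 of the 12483 genes tested passed an adjusted p of 0.05, 1335 of them higher and 1652 lower in KAT7KO. The median absolute log2 fold change of these genes was 0.39, which is 1.31-fold. A log2 fold change of at least 1 was reached by 73 higher and 289 lower genes, and 63 and 224 of these had a mean under 5 CPM (counts scaled to library size). The 3 values of each genotype did not overlap for 5124 genes (41.0%), against 10% by chance. Leaving out 1 KAT7KO library brought the counts to between 663 and 740 higher and between 1071 and 1139 lower, and leaving out Ctrl replicate 2 brought them to 834 and 1180. Asking for a change over 1.2-fold left 199 higher and 641 lower genes.

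Kat7 itself (ENSMUSG00000038909) was checked first. Its level was 73.2, 70.3 and 69.0 CPM in the Ctrl libraries and 41.4, 42.2 and 38.2 CPM in the KAT7KO libraries. It fell by 0.80 on the log2 scale (SE 0.06, adjusted p = 9.63e-07), to 57.3% of Ctrl with a 95% interval of 52.2% to 62.9%. The values are totals over the gene, and the labels do not say which part of it was deleted or in which cells. In the authors' deposited table its log2 fold change was -0.80 with an adjusted p of 2.53e-21. Ccar2 (ENSMUSG00000033712), which encodes a regulator of the deacetylase SIRT1, stood at 30.6 ± 3.87 CPM in Ctrl and 25.7 ± 1.24 CPM in KAT7KO (SD, n = 3). Its log2 fold change was -0.25 (SE 0.09, 95% interval -0.45 to -0.06) and its adjusted p, 0.0604, missed the threshold. Ctrl replicate 1 held the highest Ccar2 value, 35.0 CPM. Without that library the log2 fold change was -0.15 (adjusted p = 0.177), and without Ctrl replicate 3 it was -0.32 (adjusted p = 0.0192).

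**Figure D1:**
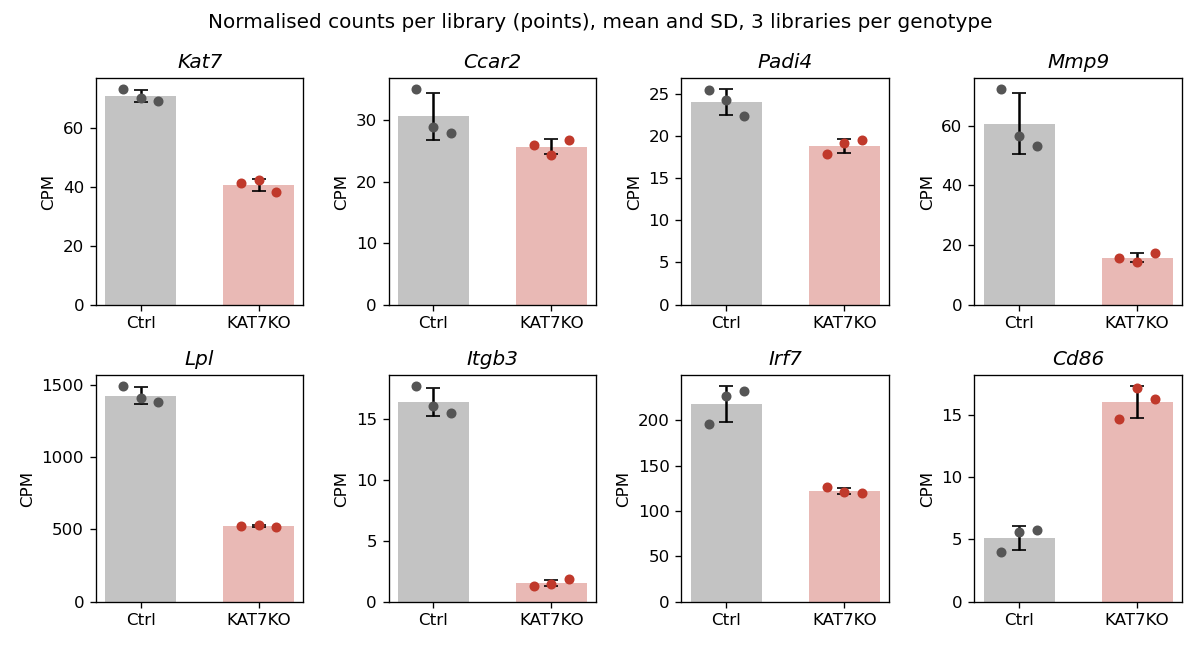
Normalised counts (CPM, linear axes from 0) of 8 genes in Ctrl and KAT7KO macrophages; points are libraries, bars are means and whiskers are SDs of 3 libraries. Kat7 lay between 38.2 and 42.2 CPM in the KAT7KO libraries and between 69.0 and 73.2 CPM in the Ctrl libraries.

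The genes with the largest falls, by the naming rule, were led by Eef1a2, a translation elongation factor best known from neurons and muscle, and by Itgb3, the integrin beta chain that pairs with the alpha-V and alpha-IIb chains. Eef1a2 went from 11.3 to 0.802 CPM (log2 fold change -3.81, SE 0.19, adjusted p = 9.68e-09). Itgb3 went from 16.4 to 1.52 CPM (log2 fold change -3.43, SE 0.15, adjusted p = 2.39e-09). Cdkn1c, which encodes the cell cycle inhibitor p57 and is expressed from the maternal allele, fell from 50.4 to 10.9 CPM, the highest Ctrl level among the 10. Arfgef3 (-2.43), Bex1 (-2.27), Sntb1 (-2.19), Mfng (-2.16), Gspt2 (-2.16), Arap3 (-2.15) and Tenm4 (-2.01) completed the 10. Mfng encodes a glycosyltransferase that modifies Notch receptors. The 10 largest rises were mostly of genes with few counts in Ctrl. Aqp9, a channel for water and glycerol, rose by 2.20 on the log2 scale from 0.585 to 2.70 CPM, and Bmx, a Tec family kinase, by 2.10. Cxcl13, a B cell chemoattractant, rose by 1.89, Selp (P-selectin) by 1.88 and Dkk2, a secreted modulator of Wnt signalling, by 1.77. Ctse, the aspartic protease cathepsin E, went from 3.67 to 12.1 CPM (log2 fold change 1.72, SE 0.13, adjusted p = 8.33e-07). The lectin-like receptor genes Clec1a (1.68) and Clec1b (1.52) and the receptor gene Pira1 (1.83) also rose. Pira1 belongs to a family of near-identical copies whose reads can be shared, so its value is uncertain.

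Genes of G2/M and mitosis fell. Of the 24 measured genes of G2/M and mitosis, 21 fell, 0 rose and 3 did not pass, and 23 were lower adjusted over the list alone. Plk1, a mitotic kinase, went from 9.97 to 4.81 CPM (log2 fold change -1.05, SE 0.14), Aurkb fell by 0.81, Top2a by 0.71 and the proliferation marker Mki67 by 0.66 on the log2 scale. The list's median was -0.68, and camera placed it below the other genes (adjusted p = 3.07e-11, and adjusted p = 0.0299 with an estimated correlation). Of 28 measured genes of replication licensing and S phase, 7 fell and 1 rose, as they did adjusted over the list alone, and 20 did not pass. Rrm2, a ribonucleotide reductase subunit, fell by 0.76, Uhrf1 by 0.71, and the MCM helicase subunit genes Mcm7 and Mcm6 by 0.36 and 0.34, while Orc2, an origin recognition gene outside the naming rule, rose by 0.33. This list passed at an adjusted p of 0.0144 and lost its call with an estimated correlation (adjusted p = 0.208 with an estimated correlation). The estimate was -0.03, below the preset 0.01, so a higher correlation among its members does not account for the loss. Of 10 measured Hox and progenitor genes 4 fell and 0 rose, with the same numbers adjusted over the list alone, and Myc, Meis1 and Cd34 had log2 fold changes of -0.68, -0.69 and -0.50. That list had a median of -0.41 and an adjusted p of 0.0211 (adjusted p = 0.328 with an estimated correlation). It missed the threshold without Ctrl replicate 1 (adjusted p = 0.0514), without Ctrl replicate 2 (0.138) and without KAT7KO replicate 2 (0.0651).

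Targets of p53 went both ways, with 6 of 22 higher and 6 lower, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.753). Sesn2 rose by 0.70, Gdf15 by 0.57 and the cell cycle inhibitor Cdkn1a by 0.47 on the log2 scale, and Phlda3 fell by 0.77. The median was 0.04 and camera's direction up, while the mean was -0.01.

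Interferon-response genes fell as a group. Of 28 measured members of the type I interferon list, 19 fell, 0 rose and 9 did not pass, and 22 were lower adjusted over the list alone. Irf7, a transcription factor that amplifies interferon production, went from 218 ± 19.6 to 122 ± 3.43 CPM (SD, n = 3; log2 fold change -0.84, adjusted p = 7.24e-07). Oasl2 fell by 1.00, Oas3 by 0.81 and the DNA sensor family gene Ifi204 by 0.46 on the log2 scale. Oas and Ifi200 family members are close copies, and reads can be shared among them. The list had a median of -0.49 and an adjusted p of 7.89e-10, which became 0.0299 with an estimated correlation. Inflammatory genes driven by NF-kB gave 6 lower and 1 higher of 18 measured, or 7 and 1 adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0502). It passed with the replicate block (0.0244), with DESeq2 size factors (0.0483), with the length trend removed (0.00608), without Ctrl replicate 1 (0.0424) and without KAT7KO replicate 3 (0.0257). It did not pass when gene correlation was estimated (adjusted p = 0.328 with an estimated correlation, and 0.226 with the length trend also removed). Ptgs2, the inducible cyclooxygenase, went from 7.66 to 2.88 CPM (log2 fold change -1.41), and Ccl2, Nfkbiz and Ccl5 fell by 0.59, 0.57 and 0.54. Sod2, outside the naming rule, was the 1 that rose, by 0.20. Il1b, Il6, Il12b and Nos2 had too few counts to be tested. Of 15 measured immediate-early and heat shock genes, which also respond to cell handling, 7 fell, among them Fos (-0.68), Egr1 (-0.67), Hsph1 (-0.40) and Zfp36 (-0.31), and Junb, outside the naming rule, rose by 0.15. Adjusted over the list alone the numbers were 7 and 2, and the list's adjusted p was 0.0583 (0.0435 without Ctrl replicate 1, 0.0449 without KAT7KO replicate 1, and adjusted p = 0.328 with an estimated correlation).

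Of 18 measured genes of the extracellular trap machinery, 7 fell, 2 rose and 9 did not pass, or 8 and 3 adjusted over the list alone. Mmp9, a secreted gelatinase, went from 60.6 ± 10.1 to 15.7 ± 1.58 CPM (SD, n = 3; log2 fold change -1.95, SE 0.12, adjusted p = 1.69e-07). Mmp12, the macrophage elastase, went from 1758 to 1270 CPM (-0.47), Ripk3, a kinase of necroptosis, fell by 0.77, and Rac2, a GTPase of the phagocyte NADPH oxidase, by 0.30. Other members past the threshold were chosen for mention after their values were seen. Among them were Padi4 (-0.35, 78.4% of Ctrl, 95% interval 69.2% to 88.8%), Prkcb (-0.30) and Mlkl (-0.29), which fell, and the oxidase subunit gene Cybb (0.16), which rose. The list's median was -0.13 and its adjusted p was 0.0930. With a gene-length trend removed it passed (0.0338), as it did without Ctrl replicate 1 (0.0409) and without KAT7KO replicate 1 (0.0495). It did not pass with correlation estimated (adjusted p = 0.328 with an estimated correlation, and 0.226 with the length trend also removed). Mpo, Elane and Cxcr2, genes of neutrophil traps, had too few counts to be tested.

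The list for clearance of extracellular DNA gave 5 lower and 0 higher of 8 measured, with the same numbers adjusted over the list alone. The complement genes C1qa and C1qc went from 295 to 168 CPM (-0.81) and from 540 to 347 CPM (-0.64), the lysosomal nuclease gene Dnase2a fell by 0.32, and C1qb, outside the naming rule, by 0.34. The remaining one that fell, Plin2 (-0.30), encodes a lipid droplet coat protein and had been put on this list in error. The list's adjusted p was 0.0113, or 0.0318 without Plin2, a setting chosen after its value was seen. The call was lost with an estimated correlation (adjusted p = 0.475 with an estimated correlation) and without KAT7KO replicate 3 (0.0534). Dnase1l3 had too few counts to be tested.

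**Figure D2:**
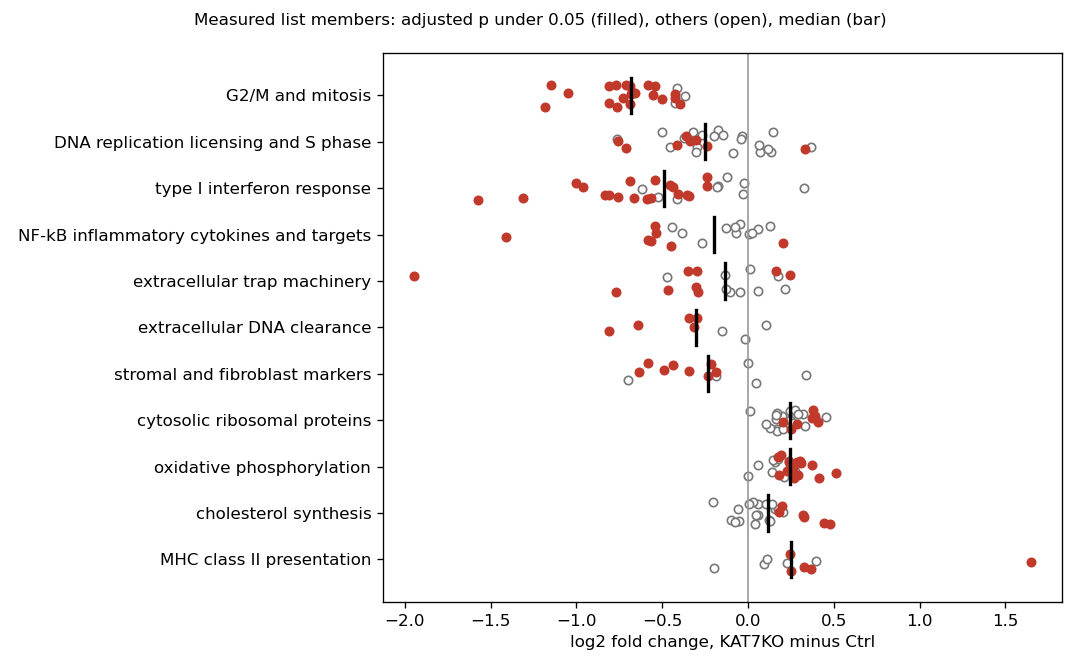
Log2 fold changes (KAT7KO minus Ctrl) of the measured members of 11 gene lists; filled points passed an adjusted p of 0.05, open points did not, and bars are list medians. The median was -0.68 for G2/M and mitosis, -0.49 for the interferon list and 0.24 for oxidative phosphorylation.

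Genes of lipid handling changed in both directions. Lpl, which encodes lipoprotein lipase, fell from 1425 ± 58.1 to 523 ± 6.11 CPM (SD, n = 3; log2 fold change -1.45, SE 0.05), and its adjusted p of 3.71e-10 was the smallest of all genes. The scavenger receptor genes Marco and Cd36 fell by 1.67 and 0.44 on the log2 scale. Of 18 measured genes of lipoprotein uptake and lipid handling 5 fell and 5 rose, or 5 and 6 adjusted over the list alone, and the list did not pass (adjusted p = 0.602). Plin2 and Msr1 were the others that fell, and those that rose were Olr1, Stab1, Cxcl16, Fabp5 and Cd9, and Msr1 and these 5 lie outside the naming rule. Cholesterol synthesis gave 6 higher and 0 lower of 24, or 7 and 0 adjusted over the list alone. Mvd rose by 0.48, Sc5d by 0.45, Msmo1 by 0.33 and Fdps by 0.32, and the list passed at 0.00841 (adjusted p = 0.208 with an estimated correlation). Among 17 measured genes of cholesterol efflux and LXR targets 3 rose and 0 fell by either adjustment, counting those adjusted over the list alone, and the list did not pass with camera (adjusted p = 0.143) except without Ctrl replicate 1 (0.0435; adjusted p = 0.328 with an estimated correlation and all libraries). Apoe went from 8029 to 9164 CPM (0.19), the transporter gene Abcg2 rose by 0.54, and Abcg1 rose by 0.14 with an adjusted p of 0.0388. Abcg1 lost its call with the replicate block (0.0659), upper-quartile factors (0.0655), no filter (0.0529) or the filter at 5 CPM (0.0593), and without Ctrl replicate 2 or any 1 of the KAT7KO libraries. Apoe lost its call without Ctrl replicate 2 (0.0558) or KAT7KO replicate 3 (0.0589).

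Antigen presentation genes of MHC class II rose in 5 of 10 measured members, and 0 fell, with the same numbers adjusted over the list alone. Cd86 went from 5.10 ± 0.993 to 16.0 ± 1.28 CPM (SD, n = 3; log2 fold change 1.65, adjusted p = 1.69e-06). H2-DMb1 rose by 0.37, the invariant chain gene Cd74 by 0.33, H2-Ab1 by 0.25 and H2-Aa, outside the naming rule, by 0.25. B cells also express MHC class II genes, and the B cell markers Ms4a1 (1.70) and Bank1 (0.97) rose in the same libraries. The list passed at 0.00347 (adjusted p = 0.208 with an estimated correlation). For MHC class I, 2 of 11 genes rose and 2 fell, or 3 and 3 adjusted over the list alone. The peptide transporter genes Tap2 and Tap1 fell by 0.51 and 0.45, and Psmb10 and Erap1 rose by 0.35 and 0.19. Without KAT7KO replicate 1 neither rise passed, and Erap1 also failed with any other library left out except Ctrl replicate 1, and with DESeq2 (0.0536), upper-quartile factors (0.0567) or the filter at 5 CPM (0.0673). That list's adjusted p was 0.924, with camera's direction up, a median of -0.0035 and a mean of -0.03.

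Macrophage identity genes gave 4 lower and 1 higher of 20 measured, also adjusted over the list alone, and the list did not pass (adjusted p = 0.753; median 0.0033, mean -0.06, camera's direction down). Lyz2, the lysozyme gene of myeloid cells, went from 28853 ± 5251 to 17980.5 ± 401 CPM (SD, n = 3; log2 fold change -0.68, adjusted p = 0.00521). Its Ctrl values were 22887, 30896 and 32774 CPM, the lowest in replicate 1. With no filter on low counts its adjusted p was 0.0546, and reads may be shared with its copy Lyz1. Itgam fell by 0.42 and Fcgr3 by 0.27, and Cebpa, outside the naming rule, rose by 0.16. Of 16 alternative activation genes 5 rose and 3 fell, likewise adjusted over the list alone (adjusted p = 0.385). Chil3 rose by 0.72, Klf4 by 0.65 and Clec10a by 0.44, while Egr2 fell by 0.48. Beyond the naming rule, Mgl2 and Ccl24 rose, and Retnla and Tgm2 fell. Chemotactic receptor genes gave 5 lower and 4 higher of 14 by both adjustments, counting those adjusted over the list alone (adjusted p = 0.361). C5ar1, the receptor gene for complement C5a, went from 251 to 128 CPM (-0.97) and Ccr1 from 62.9 to 32.0 CPM (-0.98), whereas Cxcr4 went from 143 to 221 CPM (0.63). C3ar1 and Ptafr also fell, and Fpr1, Fpr2 and P2ry14 also rose, beyond the naming rule.

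Lysosome and phagocytosis genes gave 9 higher and 5 lower of 24, with the same numbers adjusted over the list alone (adjusted p = 0.224). Those that fell included genes of bridging molecules and a receptor for apoptotic cells: Gas6 by 0.77, its receptor gene Axl by 0.55 and Mfge8 by 0.37. Ctsl and Tfe3, beyond the naming rule, were the others. Osteoclast genes also split. Acp5 and Ctsk, which encode lysosomal enzymes of osteoclasts and macrophages, rose by 0.67 and 0.56, whereas Itgb3, Mmp9 and, beyond the naming rule, Dcstamp fell. That made 2 higher and 3 lower of 7 measured, also adjusted over the list alone (adjusted p = 0.361).

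Oxidative phosphorylation genes encoded in the nucleus rose in 17 of 26 measured members and fell in 0, or 21 and 0 adjusted over the list alone. Cox4i1 went from 414 ± 64.3 to 590 ± 21.9 CPM (SD, n = 3; log2 fold change 0.51), Cyc1 rose by 0.31 and Uqcrc2 by 0.29. The list's median was 0.24 and its adjusted p 1.92e-06 (adjusted p = 0.451 with an estimated correlation). Cytosolic ribosomal protein genes, whose reads can be shared with processed pseudogenes, moved the same way, with 7 of 25 higher and 0 lower, or 15 and 0 adjusted over the list alone. Rpl7 rose by 0.41, Rpl5 by 0.39, Rps4x by 0.29 and Rpl4, whose call needs all 3 KAT7KO libraries, by 0.21, with a median of 0.25 and an adjusted p of 6.60e-05 (adjusted p = 0.529 with an estimated correlation). Both lists hold short genes, and Ctrl replicate 1 stood apart by gene length. Ribosomal protein genes took 2.82% of its counts, against 3.37% and 3.65% in the other Ctrl libraries and 3.75% to 3.95% in KAT7KO. The mean log2 CPM of the oxidative phosphorylation list was 6.38, 6.54 and 6.63 in Ctrl and 6.75, 6.77 and 6.76 in KAT7KO. Of 13 mitochondrially encoded transcripts only mt-Nd3 passed, also adjusted over the list alone, with a fall of 1.17, and the list's adjusted p was 0.405. The list's mean log2 CPM was lower in every KAT7KO library (6.95, 6.95 and 6.97) than in the Ctrl libraries (7.02, 7.05 and 7.20). That mean includes mt-Nd3, and the list's median log2 fold change was -0.04 against a mean of -0.14. With the length trend removed the list passed as lower (adjusted p = 0.00608, but adjusted p = 0.269 with an estimated correlation), and mt-Co1, at -0.04 and an adjusted p of 0.512 before, was called (0.00214), as it was without Ctrl replicate 1 (0.00625).

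**Figure D3:**
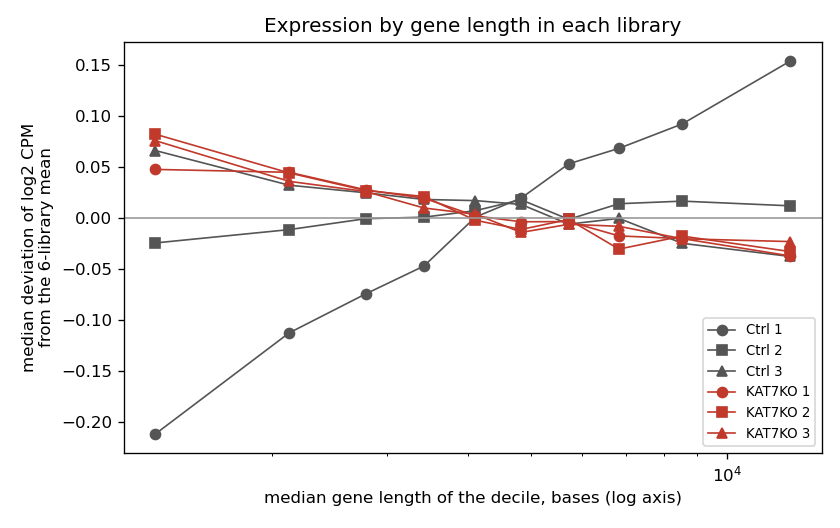
Median deviation of log2 CPM from the 6-library mean (y axis) for genes in 10 bins of gene length (x axis, log scale, bases), 1 line per library. Ctrl replicate 1 ran from -0.21 for the shortest genes to 0.15 for the longest, while the KAT7KO libraries ran from between 0.05 and 0.08 to between -0.04 and -0.02.

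The first principal component, with 54.6% of the variance, separated the genotypes, and the next, with 13.6%, separated Ctrl replicate 1 (19.4) from Ctrl replicates 2 (-6.25) and 3 (-16.7). The rank correlation across genes of a library's deviation with gene length was 0.38 in Ctrl replicate 1, 0.06 and -0.15 in the other Ctrl libraries, and -0.18 to -0.15 in KAT7KO. Across genes the fold change and length correlated at -0.21, and genes are not independent replicates. Without Ctrl replicate 1 there were 1708 higher and 1820 lower genes, and with the length trend removed 1685 and 1831, both settings giving 2763 and 2812 of the 2987 genes again.

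Among other metabolic and stress genes, 6 of 22 measured genes of glycolysis and lactate fell and 1 rose, or 7 and 3 adjusted over the list alone. Aldoc went from 11.4 to 5.25 CPM (-1.12), Pfkm fell by 0.70 and Pfkfb3 by 0.28, while Pdk1, a brake on pyruvate entry into mitochondria, rose by 0.40. Ldha, which makes lactate and lies outside the naming rule, had a log2 fold change of 0.13 and an adjusted p of 0.0544. The list did not pass (adjusted p = 0.602), and its median of -0.02 and camera's direction, down, differed in sign from its mean of 0.04. Its largest log2 fold change, 2.90, was that of Gapdh, named after its value was seen, which did not pass (adjusted p = 0.0870; 58, 445 and 58 counts in Ctrl and 1815, 1256 and 993 in KAT7KO). Gapdh has many processed pseudogenes with which reads can be shared. Of 18 genes of the unfolded protein response 4 rose and 3 fell, or 5 and 4 adjusted over the list alone (adjusted p = 0.160). These were Atf4 and genes that its product or the unfolded protein response induces, with Chac1 up by 1.44, Trib3 by 0.93, Herpud1 by 0.36 and Atf4 by 0.29. The 3 that fell, Atf3, Edem1 and Hyou1, lie beyond the naming rule. The chaperone gene Hspa5, named after its value was seen, was at 0.02 (adjusted p = 0.815). Oxidative stress genes gave 5 lower and 3 higher of 16, as they did adjusted over the list alone (adjusted p = 0.813; median -0.0063, mean 0.0052, camera's direction down). Cat fell by 0.45, Hmox1 by 0.29 and Gsr by 0.23 (adjusted p = 0.0597 without KAT7KO replicate 1), and Mgst1 rose by 0.45. Beyond the naming rule Txnrd1 and Srxn1 fell, and Slc7a11 and Gpx4 rose.

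Genes of the enzyme's own family went both ways. Of 12 measured partners and relatives of MYST enzymes, Kat8 (0.38), Brd1 (0.25) and Kat5 (0.24) rose and Jade1 (-0.31), a scaffold gene of KAT7 complexes, fell, also adjusted over the list alone. The list's adjusted p was 0.926, with a median of -0.03, a mean of 0.0036 and camera's direction up. Among 17 other lysine acetyltransferase and deacetylase genes 3 rose and 1 fell, or 4 and 2 adjusted over the list alone (adjusted p = 0.469). Aars, an alanyl-tRNA synthetase gene whose product has been described as a lactyltransferase, rose by 0.28, Kat2b by 0.24 and Sirt2 by 0.21, and Sirt6 fell by 0.37. Of these 8 calls only Aars and Sirt2 kept theirs whichever library was left out: Brd1 failed without Ctrl replicate 2 or KAT7KO replicate 1 or 2, Kat8 without Ctrl replicate 2 or any 1 of the KAT7KO libraries, and Kat5 without Ctrl replicate 2 or KAT7KO replicate 2 or 3. With a library left out, Jade1 held only without Ctrl replicate 2, Kat2b only without Ctrl replicate 1, and Sirt6 without Ctrl replicate 1 or KAT7KO replicate 1. All 3 were also lost with DESeq2, Sirt6 with the replicate block, and Jade1 with the length trend removed.

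Markers of other cell types were measured as a check on the cultures. Stromal and fibroblast markers were well above the detection limit and lower in KAT7KO, with 8 of 13 lower and 0 higher, likewise adjusted over the list alone. Dcn went from 149 to 118 CPM (-0.35), Pdgfra from 102 to 67.9 CPM (-0.58), Col6a1 from 81.2 to 57.7 CPM (-0.49) and Cxcl12 from 14.3 to 9.17 CPM (-0.64). The list's adjusted p was 0.00436 (adjusted p = 0.328 with an estimated correlation), and it fell in the same libraries as the cell cycle and progenitor genes. Of 3 measured endothelial markers Eng fell by 1.57 and Kdr by 0.49, as they did adjusted over the list alone (adjusted p = 0.160). B cell markers had low levels. Bank1 went from 1.71 to 3.34 CPM (0.97) and Ms4a1 from 0.421 to 1.39 CPM (1.70), and 2 of 4 measured rose and 0 fell, or 3 and 0 adjusted over the list alone. The list passed at 0.01002 (adjusted p = 0.208 with an estimated correlation), and Pax5 had too few counts to be tested.

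Neutrophil markers gave 3 higher and 1 lower of 6, also adjusted over the list alone (adjusted p = 0.361). S100a8 rose by 0.86 from 6.07 CPM in Ctrl, Mmp8 rose by 0.47 and Csf3r by 0.34, and Chil1 fell by 0.76. Dendritic cell markers gave 2 lower of 6, or 3 adjusted over the list alone (adjusted p = 0.160). Fscn1 fell by 0.55 and Itgax by 0.20 with an adjusted p of 0.0469, a call lost without Ctrl replicate 2 or any 1 of the KAT7KO libraries, with DESeq2 or its size factors, with limma-voom, and with the length trend removed. T and NK cell markers gave 0 higher and 0 lower of 3, also adjusted over the list alone (adjusted p = 0.867), with Cd4 at 0.69 (adjusted p = 0.0997, and 0.0220 without KAT7KO replicate 1) and Lck at 0.19 (0.696). Among 4 mast cell and basophil markers Tpsb2 fell by 1.07 (adjusted p = 0.0366; list adjusted p = 0.174), also adjusted over the list alone. That call was lost with DESeq2 (0.0741) and without Ctrl replicate 1 or 2 or KAT7KO replicate 2 or 3. Of 2 measured erythroid and megakaryocyte markers, too few for a test of the list, Pf4 fell by 0.64, also adjusted over the list alone, and Car2 was at -0.71 (adjusted p = 0.322). The Y-linked gene Ddx3y stood at 28.2 CPM in Ctrl and 32.4 CPM in KAT7KO (adjusted p = 0.0828, and 0.0321 without Ctrl replicate 3), and Eif2s3y at 24.9 CPM in KAT7KO with a log2 fold change of -0.0040.

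Of 36 lists fixed before the data were examined, 34 were tested and 11 passed, 5 higher and 6 lower. Interferon response and G2/M were the 2 that passed with an estimated correlation. By the authors' deposited values, 2435 genes had an adjusted p under 0.05, 1158 higher and 1277 lower. Of these, 2380 were also called here, all 2380 with the same sign, and 55 were not.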

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

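Removing the gene-length trend and leaving Plin2 out of its list were chosen after the data were seen, and the other alternatives before. The counts of 1335 higher and 1652 lower genes ranged, with a library left out, from 663 to 1708 and from 1071 to 1820. Without KAT7KO replicates 1, 2 and 3 the higher count was 715, 663 and 740, and without Ctrl replicate 2 it was 834. Fewer libraries were tested in each of these, but also without Ctrl replicates 1 and 3, where the higher count was 1708 and 1706. Why the KAT7KO libraries weighed more was not tested. The glmTreat test for a change over 1.2-fold, which asks more of each gene, gave 199 and 641. DESeq2 gave 1159 and 1277, and every gene shared with the first fit had the same sign under each alternative fit. With the replicate number as a block (the replicate block) there were 1290 and 1522, the NF-kB list passed (adjusted p = 0.0244), and Abcg1 (0.0659) and Sirt6 lost their calls. The same-number libraries did not vary together (correlations -0.0044, 0.0059 and 0.02). The labels do not say what a shared number means, and these correlations cannot show that such libraries had no litter or day in common.

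Kat7 kept its call under every alternative fit, from -0.83 to -0.76 on the log2 scale. Ccar2 stayed negative and passed with upper-quartile factors (-0.27, adjusted p = 0.0469), with no filter (-0.25, 0.0414) and with the length trend removed (-0.23, 0.0497). With a library left out it ranged from -0.32 to -0.15, with adjusted p from 0.0192 to 0.206, and it passed only without Ctrl replicate 3. Over all alternatives its adjusted p lay between 0.0192 and 0.206. The cause was not tested. Of 136 other named genes that passed, 120 did so under every alternative that gave a value, and 8 of the 16 others failed only with a library left out.

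The 11 lists past the threshold became 2 with an estimated correlation and 24 with fry, which does not compare a list with other genes, and 2 with both the length trend removed and an estimated correlation. The estimate was 0.97 for ribosomal proteins and 0.54 for oxidative phosphorylation. It lay below the preset 0.01 for S phase (-0.03), cholesterol synthesis (-0.03) and B cell markers (-0.099). For these a higher correlation does not account for the lost call. The estimates for G2/M (-0.0096) and interferon response (-0.025) also lay below the preset. Their unadjusted camera p still rose, from 9.03e-13 to 0.00137 and from 4.64e-11 to 0.00176. This setting therefore raised p without a higher correlation, so a call lost under it does not by itself show correlated genes. What else raised p was not tested. Removing the trend alone gave 15, with the trap machinery, NF-kB, immediate-early and mitochondrially encoded lists added, all lower. Leaving out a library gave 10 to 14. No list or named gene that passed in either setting changed direction. With these depths, genes under 5 CPM carry most of the large fold changes and the widest errors.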

Other observations

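All lists in this and the next paragraph were written after some members' values had been seen, so their tests are not independent of the data. Imprinted genes, which are expressed from 1 parental allele, were listed after Cdkn1c had been seen to fall: of 16 measured, 9 fell, 0 rose and 7 did not pass, and 9 were lower adjusted over the list alone. Cdkn1c fell from 50.4 to 10.9 CPM, Grb10 by 0.53 on the log2 scale, H19 by 1.03 and Cd81 by 0.35, while Dlk1 (-2.83), Meg3 (-2.37), Peg3 (-1.73) and Plagl1 (-1.52) lay under 1 CPM on average. Camera gave an adjusted p of 8.86e-05 over the 4 added lists (adjusted p = 0.0900 with an estimated correlation). Impact and Gnas, at -0.04 and -0.02, did not pass. Stromal markers, which some of these genes accompany in mesenchymal cells, fell in the same libraries, with Dcn at -0.35 and Pdgfra at -0.58.

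Cytosolic aminoacyl-tRNA synthetase genes rose in 11 of 18 measured members and fell in 0, also adjusted over the list alone. Yars rose by 0.48, Nars by 0.39, Sars by 0.34 and Aars by 0.28 (list adjusted p = 7.14e-05, and adjusted p = 0.0900 with an estimated correlation). Of 11 genes of serine and one-carbon synthesis 2 rose, Phgdh by 0.86 and Mthfd2 by 0.66, and 0 fell, with the same numbers adjusted over the list alone, and the list did not pass (adjusted p = 0.178 with an estimated correlation). Among 13 genes of iron uptake and storage 4 fell and 2 rose by either adjustment, including that adjusted over the list alone, and this list did not pass either (adjusted p = 0.178 with an estimated correlation). Tfrc, the transferrin receptor gene, fell by 1.02, while the ferritin genes Fth1 (-0.03) and Ftl1 (0.00018) did not pass.

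Of the tests that follow, those on the remaining Kat7 reads and on a Cre allele at Lyz2 were chosen after the results were seen. The margin by the spread between libraries was also added then to the tests of the lists. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The genotype split gave 2987 genes and the highest other split 1, so 1 of 10 splits was as large. Every other split mixes the genotypes, which widens the spread within its groups and lowers its count, so the contrast does not measure chance. For the lists the genotype split gave 11 and the highest other 8, again 1 of 10. Single lists stood out less than that total. Among the lists that passed for the genotype, another split gave a smaller adjusted p for ribosomal proteins (2.97e-09 against 6.60e-05), DNA clearance (0.00605 against 0.0113), Hox and progenitor genes (0.00326 against 0.0211) and B cell markers (0.0090 against 0.01002). The same held for some lists that had not passed, and another split called the mast cell (0.00326), mitochondrially encoded (0.0350) and NF-kB (0.0458) lists. Of the 9 other splits, G2/M passed in 9, interferon response in 8, ribosomal proteins in 7 and oxidative phosphorylation in 6, and each of those splits keeps an imbalance of the genotypes.

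The rise of oxidative phosphorylation and ribosomal protein genes in KAT7KO may partly reflect that Ctrl replicate 1 was poor in short transcripts. For oxidative phosphorylation the tables argue against this as the whole cause. The list's median, 0.24, was 0.18 with the length trend removed (adjusted p = 4.82e-06) and 0.17 without Ctrl replicate 1 (adjusted p = 3.65e-06). Each lay above 0.5 of the first value by more than the SE between libraries (0.03 and 0.05). The SEs in this paragraph are of the genotype difference in the list's mean log2 CPM, not of the median. For oxidative phosphorylation that difference was 0.24, and 0.19 with the trend removed. The test of the list is weaker than these values: it did not pass with the trend removed and correlation estimated (adjusted p = 0.227 with an estimated correlation), nor before the removal (adjusted p = 0.451 with an estimated correlation). For ribosomal proteins the median of 0.25 became 0.16 (adjusted p = 3.57e-04; SE 0.09) and 0.14 (adjusted p = 4.03e-04; SE 0.06), which is too close to that bound to decide. This list did not pass with the trend removed and correlation estimated (adjusted p = 0.607 with an estimated correlation), nor with fry (0.142). A difference in library quality that follows the genotype stays open for both, as does an effect of the genotype.

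Kat7 RNA remained at 57.3% in KAT7KO, and a candidate explanation is that a share of the cells escaped deletion. If these were the whole source, a gene that depends on KAT7 within the cell could not fall much below that level, yet 26 genes fell by more than the upper limit of the Kat7 fall (0.94 on the log2 scale, glmTreat), among them Eef1a2 at 7.12% of Ctrl. The bound holds only if escaped and deleted cells express those genes alike and both genotypes' cultures hold the same mix of cells. It also fails if those genes respond to signals between cells. Stromal markers fell in the same libraries, so the mix may have differed, and the 26 genes do not decide whether escaped cells were the whole source. Transcripts of a deleted allele that still carry other exons may also be counted. Gene totals hold no exon values, so this cannot be told apart from a partial loss.

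The fall of Lyz2 is a separate case, because a Cre recombinase placed in that gene is a common way to delete genes in macrophages, and such an allele may lower Lyz2 itself. The labels give no deletion method. Lyz2 was at 62.3% of Ctrl, with a 95% interval of 51.4% to 75.5%, which such an allele could give. Its neighbour and copy Lyz1 was at 66.0%, and reads may be shared between them. Without exon values this cannot be told apart from regulation by KAT7. The length trend is argued against, since the fall was -0.79 with the trend removed (adjusted p = 3.21e-04).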
